A study of Picosynechococcus sp. PCC 7002 and Shewanella sp. W3-18-1 and Picosynechococcus sp. PCC 7002
Shewanella sp. W3-18-1 with 10 samples.

How the data were processed

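Transcripts of the cyanobacterium Synechococcus sp. PCC 7002, a euryhaline unicellular phototroph, and of Shewanella putrefaciens W3-18-1, a facultatively aerobic heterotroph, were measured in chemostat cultures. The series held 10 samples, which came from 8 libraries and gave 11 organism profiles, because the reads of each co-culture library had been counted against both organisms. Per the labels, total RNA was extracted with Trizol, treated with DNase, prepared with the SOLiD Total RNA-Seq kit and sequenced on a SOLiD 5500XL instrument. Per the growth protocol, axenic Shewanella grew on 5 mM lactate. Per the labels, axenic Synechococcus grew on 8 mM bicarbonate, and the co-cultures had 5 mM lactate or 8 mM bicarbonate as the only carbon source, in medium with 17 mM ammonium chloride and 10 µM ferric chloride.

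The authors deposited 1 file per profile, with raw counts of reads per gene, and the values used here are these deposited counts. An RPKM column beside them was not used. A placeholder entry in the files names LifeScope, but aligner settings, the counting step and the use of strand were not stated. The 129 Shewanella RNA genes were each listed as gene and as exon with the same count, and the exon copies were left out. The files gave locus tags and positions but no products. Gene symbols came from the RefSeq annotation of each strain, matched by locus tag or position, which gave a symbol to 706 of 3188 coding genes of Synechococcus and to 383 of 4088 of Shewanella. Genes without a symbol are given by locus tag only.

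The rRNA, tRNA and other RNA genes (50 in Synechococcus, 129 in Shewanella) were left out of every test, and levels are given as CPM, a gene's reads scaled to a library total of 1000000 coding reads. Coding reads ranged from 232209 to 7450077 for Synechococcus and from 5583 to 6393687 for Shewanella. A count of 0 allows up to 3 counts, which is 537 CPM in the light-limited Shewanella profile and 0.403 CPM in the deepest Synechococcus profile. Intervals are 95% intervals, exact (Clopper-Pearson) for shares and conditional exact for ratios of 2 counts. Intervals and floors cover counting error only.

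No condition had a second library. Conditions were therefore pooled into classes for the tests, and the spread in these tests is that between conditions, not between repeat cultures. Culture class coincided with the cultivation run in the sample titles, and so did O2 level in the axenic Synechococcus cultures, whereas light was balanced within run. Tests used edgeR 4.0.16 (quasi-likelihood fit, TMM scaling, its filter on low counts) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors of log2 changes are standard errors derived from the quasi-likelihood F statistic. The third split of the 4 axenic libraries was fitted in the same way after the light and O2 results had been seen. Its fit had a term for O2 and none for light, so its spread is the light effect shared by both O2 levels. In the fits for light and for O2, the spread is the difference of the light effect between the O2 levels. Comparisons of single libraries had no test. For these a gene was counted when its CPM differed at least 4-fold with at least 50 reads on the higher side, with lower counts held at 3.

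Gene lists (light harvesting, photosystems, carbon uptake and fixation, nitrogen, iron and phosphate uptake, tetrapyrroles, fermentation, glycogen use, cobalamin and methionine, respiration, motility, amino acid synthesis, fatty acid breakdown, ribosome, ATP synthase, chaperones, oxidative stress and others) were fixed by symbol and by product words before the data were examined. The files held no products, so the product words were not applied and members were matched by symbol alone. Lists with under 4 measured members were not tested, which left 14 lists for Synechococcus and 8 for Shewanella. Among those left out were carbon fixation, bicarbonate uptake and iron uptake in Synechococcus, and lactate use, terminal oxidases and TonB receptors in Shewanella. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. For single libraries, each list's median log2 ratio, with 0.5 added to each count, was ranked among 10000 random lists matched on mean expression. The 8 largest passing genes with a symbol in each direction were named, plus the 2 largest of each list. Any other gene named was chosen after its values were seen.

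The alternatives were DESeq2's size factors (RLE), upper-quartile scaling, no filter on low counts, DESeq2 1.42.0 in place of edgeR, RNA genes kept in the library size, leaving out each library, other class compositions, other thresholds of the 4-fold rule and, for read shares, other sets of genes. List medians with 1 or 3 added to each count, and fits for light and O2 with 1 library left out and 1 term, were computed after the data had been seen. The comparisons of lactate with the carbon-limited co-culture alone, of light within each O2 level and of lactate with both bicarbonate co-cultures in Synechococcus by the 4-fold rule were added after the data had been seen. The procedures were tested on simulated counts with known changes. Tables and figures were made with numpy, pandas, scipy and matplotlib.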

Results

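Gene expression was measured in Synechococcus grown alone at 2 light levels and 2 O2 levels (4 libraries), in Shewanella grown alone (1 library), and in 3 co-cultures of both organisms. The co-cultures were fed bicarbonate under carbon limitation, bicarbonate under light limitation, or lactate. The label of the axenic Shewanella sample reads high light and high O2 and names no carbon source, so growth on lactate was taken from the growth protocol, and every comparison with that library rests on this. The design addressed how the carbon source and the direction of carbon flow affect the interaction of the organisms. Each condition had 1 library and no replicates. Coding reads of Synechococcus numbered 7450077 (high light, high O2), 7138185 (low light, high O2), 4438224 (high light, low O2) and 4681266 (low light, low O2) in the axenic libraries. They numbered 2039214 in the carbon-limited, 1803124 in the light-limited and 232209 in the lactate co-culture. Coding reads of Shewanella numbered 6393687 in the axenic library, 125840 in the carbon-limited, 5583 in the light-limited and 5696708 in the lactate co-culture.

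Which organism supplied most of the messenger RNA differed with the carbon source. Shewanella contributed 96.1% of the coding reads of the lactate co-culture. Its share was 5.81% (95% exact binomial interval 5.78 to 5.84) in the carbon-limited bicarbonate co-culture and 0.309% in the light-limited one, where 5583 reads came from Shewanella. With the RNA genes included the shares were 92.7%, 2.34% and 0.520%, and without the Shewanella tRNA gene Sputw3181_R0090, which held 42.1% of the Shewanella reads of the light-limited library, they were 92.7%, 2.07% and 0.302%. RNA genes took 79.0% of the Synechococcus reads in the carbon-limited, 65.6% in the light-limited and 84.1% in the lactate co-culture, against 31.1% to 39.5% in the axenic libraries.

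Axenic Synechococcus at high O2 had far lower levels of a cluster of neighbouring genes of tetrapyrrole synthesis than at low O2. hemN (SYNPCC7002_A1990, 2071309 to 2072706 on the minus strand of the chromosome), the oxygen-independent coproporphyrinogen oxidase, fell by 7.69 ± 0.52 on the log2 scale (SE, 2 libraries against 2, adjusted p = 1.38e-04 by edgeR). acsF (SYNPCC7002_A1992), which encodes the cyclase that forms the fifth ring of chlorophyll, fell by 7.28 ± 0.50 (adjusted p = 1.38e-04), but missed the threshold without the light term (adjusted p = 0.0675). hemN stood at 1338 and 2047 CPM in the low-O2 libraries and at 5.50 and 9.81 CPM in the high-O2 libraries. The genes beside them, SYNPCC7002_A1989 and SYNPCC7002_A1991, named here after their values were seen, fell by 6.71 ± 0.52 and fell by 7.62 ± 0.51. These 4 genes were the only ones past the threshold among 3119 tested, with 149 at an unadjusted p under 0.05 and 14 by DESeq2. In fits on 3 of the libraries without the light term, 4 genes passed when either low-O2 library was left out and 0 when either high-O2 library was (129 and 447 at an unadjusted p under 0.05), with hemN at -8.16 to -7.24.

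As a group, hydrogenase and fermentation genes were higher at high O2 (median log2 change 0.52 over 10 members, adjusted p = 0.00439 by camera, 0.718 with an estimated correlation), but 0 of the 10 passed the test of single genes. The largest changes among them, in hoxE (1.31 ± 0.40) and hoxU (1.17 ± 0.37), subunits of the bidirectional hydrogenase, did not pass and were named after their values were seen. Glycogen and oxidative pentose phosphate genes were also higher as a group (median 0.80, 9 members, adjusted p = 0.0398, 0.718 with an estimated correlation), and here too 0 members passed among all genes tested, with zwf at 1.30 ± 0.36 and glgP, glycogen phosphorylase, at 1.03 ± 0.39. The tetrapyrrole and chlorophyll list passed as lower (median -0.15, 12 members, adjusted p = 0.00932 by camera, 0.718 with an estimated correlation). hemN, at -7.69, was the member past the threshold, while 11 members did not pass and the highest stood at 0.46. Whether the list passes without hemN was not tested, so no change of the group is concluded. acsF is not a member of this list, which was matched by symbol alone. The planned product words, which might have taken it in, were not applied. With 1 library left out and no light term, the first list missed the threshold in 1 of 4 fits, the glycogen list in 4 and the tetrapyrrole list in 2. Over the lists, 1 gene passed among all genes tested and 2 when adjusted over the list alone. O2 level and cultivation run cannot be told apart here.

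The response of axenic Synechococcus to light was not the same at both O2 levels. At high O2, 77 genes differed at least 4-fold between the light levels, 66 of them higher in high light. fldA (SYNPCC7002_A1291), flavodoxin, was 102-fold higher (95% interval 68.9 to 158), and bicA (SYNPCC7002_A2371), a bicarbonate transporter, was 24.8-fold higher (22.0 to 28.0). The iron-sulfur cluster assembly genes sufD, sufC and sufB were 7.19-fold, 4.84-fold and 4.60-fold higher. sufR was 4.02-fold higher, and cruG was 5.14-fold higher on 59 against 11 reads. At low O2, 51 genes differed 4-fold, 23 higher and 28 lower in high light. There bicA was 11.2-fold lower in high light, whereas bchL, a subunit of the dark-operative protochlorophyllide reductase, and katG, the catalase-peroxidase, were 5.74-fold and 4.85-fold higher. Among the 2653 genes with at least 500 reads over the 7 Synechococcus libraries, differences of at least 4-fold went the same way at both O2 levels for 12 genes and opposite ways for 25.

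Taken over both O2 levels, edgeR called 0 genes between high and low light (60 of 3119 at an unadjusted p under 0.05, lowest adjusted p = 0.0613), and DESeq2 called 22, all higher in high light. The spread in the edgeR fit is the difference of the light effect between the O2 levels, so a reversed light effect widens it. Without the filter on low counts edgeR called 11, and in fits on 3 of the libraries without the O2 term it called 12 without the high-light low-O2 library and 0 in the other cases. None of the 14 gene lists passed (lowest adjusted p = 0.227), and 0 genes passed when adjusted over the list alone. The hydrogenase and fermentation list had a median of 0.03 and a test direction of lower. In simulated data of this size the fit found 53.7% of genes changed 4-fold. The simulated genes all had the same spread and a light effect equal at both O2 levels. The percentage thus does not hold for genes whose light effect differs between the O2 levels.

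The third way to split the 4 axenic libraries, high light with high O2 and low light with low O2 against the other 2, gave 19 genes past the threshold, 18 of them higher. bicA was higher by 4.15 ± 0.34 on the log2 scale (adjusted p = 0.0226 by edgeR). The genes with the largest changes, SYNPCC7002_A0470 (7.03 ± 0.35) and SYNPCC7002_A2287 (6.91 ± 0.38), were named after their values were seen. In high light at high O2 bicA stood at 1000.4 CPM, in low light at low O2 at 404 CPM, and in the other 2 axenic libraries at 40.3 and 36.1 CPM. This split is the difference of the light effects at the O2 levels, and it was fitted after the light and O2 results had been seen.

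**Figure D1:**
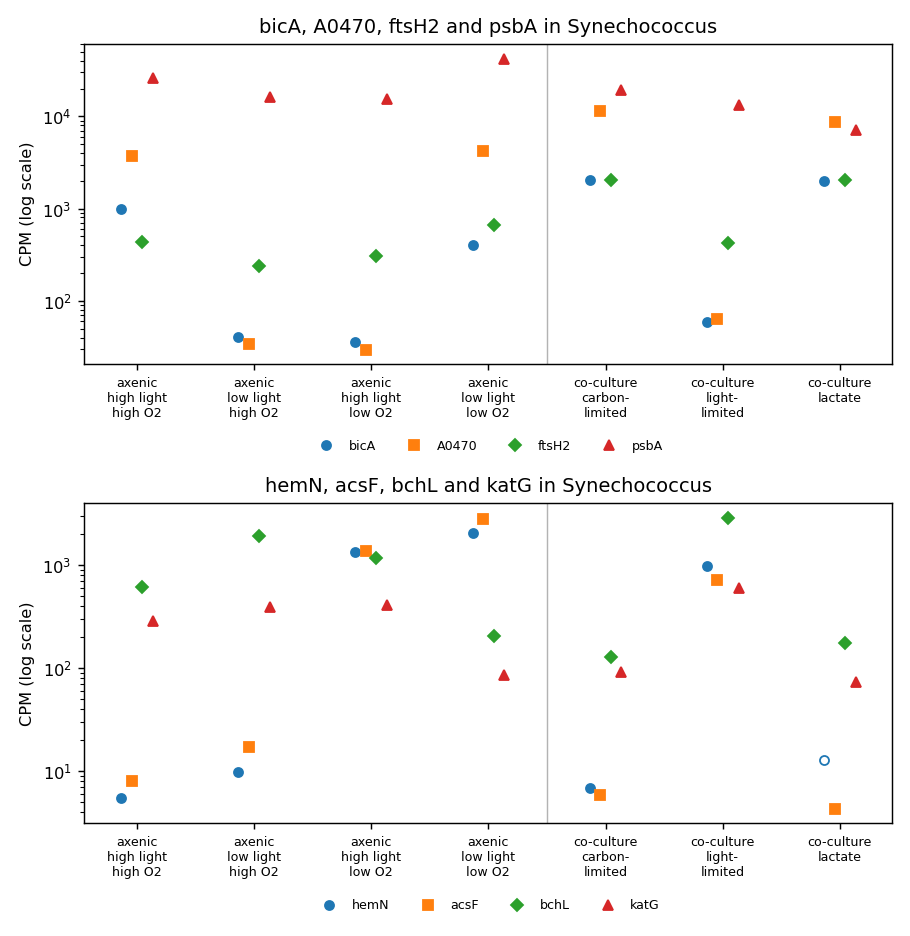
Levels of bicA, A0470, ftsH2 and psbA (upper panel) and of hemN, acsF, bchL and katG (lower panel) in the 7 Synechococcus libraries, in CPM on a log axis. Each point is 1 library, and the open symbol marks a count of 0, drawn at the 12.9 CPM that it allows; bicA stood at 2041 CPM in the carbon-limited and at 59.3 CPM in the light-limited co-culture, and hemN at 6.87 and 978 CPM.

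Between the bicarbonate co-cultures, the genes of Synechococcus that differed at least 4-fold included the bicarbonate transporter bicA and the tetrapyrrole gene hemN. Under carbon limitation bicA was 34.4-fold higher than under light limitation (95% interval 28.4 to 42.1). ftsH2 (SYNPCC7002_A0349), a thylakoid protease of photosystem repair, was 4.90-fold higher (4.53 to 5.30), and serA (SYNPCC7002_A1246), the first enzyme of serine synthesis, was 4.31-fold higher. nthB, cas1d and pdxH were 5.57-fold, 5.03-fold and 4.36-fold higher on 27 or fewer reads in the light-limited library. Under light limitation hemN was 142-fold higher (84.7 to 261), acsF 123-fold higher and bchL 22.6-fold higher. katG, mscL, a mechanosensitive channel, and gap, glyceraldehyde-3-phosphate dehydrogenase, were 6.58-fold, 4.79-fold and 4.70-fold higher.

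In all, 84 of 3188 genes were 4-fold apart, 52 higher under carbon limitation and 32 higher under light limitation. Glycogen and oxidative pentose phosphate genes had a median log2 ratio of -0.98 (carbon-limited over light-limited, 9 members), at percentile 0.05 of matched random lists. Hydrogenase and fermentation genes had a median of -0.75 (percentile 0.13), and NDH-1 genes had a median of 0.88 (percentile 99.0, 4 members). Ribosomal protein genes had a median of -0.30 (percentile 1.77, 49 members), phosphate uptake genes one of -0.67 (percentile 2.18, 4 members) and photosystem I genes one of -0.53 (percentile 2.64). Oxidative stress genes had a median of 0.57 (percentile 97.0, 5 members), opposite in direction to their member katG. Tetrapyrrole and chlorophyll genes had a median of -0.32 (percentile 9.88), with 1 of 12 members 4-fold apart. That list, matched by symbol alone, holds neither acsF nor bchL. The planned product words, among them protoporphyrin and protochlorophyllide, might have taken them in but were not applied. The median thus does not stand for the list as planned. There was 1 library on each side, so no test was made, and the threshold set the count, which was 342 genes at 2-fold and 43 at 8-fold.

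Synechococcus in co-culture had 105 genes higher and 25 lower than in axenic culture, of 3107 tested (3 libraries against 4, edgeR). kdpB (SYNPCC7002_G0059, 57241 to 59328 on the minus strand of plasmid pAQ7), the catalytic subunit of a potassium-transporting ATPase, rose by 3.92 ± 0.47 on the log2 scale (adjusted p = 0.00937). coaE, the last enzyme of coenzyme A synthesis, rose by 3.15 ± 0.44 (adjusted p = 0.0148), and serA rose by 2.86 ± 0.62 (adjusted p = 0.0436). The level of serA was 2954 CPM in the carbon-limited and 5939 CPM in the lactate co-culture. In the light-limited co-culture it was 685 CPM, little above the axenic 434 to 560 CPM. argZ rose by 2.15 ± 0.45, hflX, a ribosome-associated GTPase, by 2.10 ± 0.36, murJ, a flippase of cell wall precursors, by 1.94 ± 0.42, ccmS by 1.87 ± 0.32 and recO, a DNA repair protein, by 1.71 ± 0.39. egtB fell by 1.26 ± 0.27 and infA, a translation initiation factor, fell by 0.97 ± 0.22.

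Single members of larger groups changed between axenic culture and co-culture. Of 49 ribosomal protein genes, rplO (1.55 ± 0.30) and rplF (1.15 ± 0.21) rose and 47 did not pass. Of 4 phosphate uptake genes, phoU (1.45 ± 0.32), a regulator of phosphate uptake, rose and 3 did not pass. None of the 14 lists passed (lowest adjusted p = 0.834). Over the lists, 3 genes passed among all genes tested and 11 when adjusted over the list alone.

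Genes next to those that differed between co-culture and axenic Synechococcus mostly did not pass the test. kdpA (0.18 ± 0.39) and kdpC (-0.70 ± 0.59), which encode the other subunits of the potassium pump, did not pass. infA (SYNPCC7002_A1045) fell while secY (SYNPCC7002_A1047, 1.57 ± 0.36) and rplO (SYNPCC7002_A1048), close by on the same strand, rose; kdpA, kdpC and secY were named after their values were seen. Of the 105 genes higher in co-culture, 68 had a tested neighbour within 100 bases on the same strand, in 88 pairs; 6 of the neighbours were among the 105, and the neighbours had a median log2 change of 0.00596 against 1.61 for the genes themselves. Of the 25 lower genes, 19 had such a neighbour, in 27 pairs, and the neighbours had a median of -0.32 against -1.06 for the genes themselves.

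All 130 genes had co-culture values wholly above or below the axenic ones, as did 24.0% of all tested genes, where chance would give 2 of 35 splits, and 758 genes had an unadjusted p under 0.05. edgeR called 0 genes without the high-light high-O2, the low-light high-O2 or the low-light low-O2 axenic library (771, 588 and 647 at an unadjusted p under 0.05), 10 without the high-light low-O2 library, 8 without the carbon-limited co-culture, 21 without the lactate co-culture and 356 without the light-limited co-culture, and DESeq2 called 364 with every library. Culture class coincided with cultivation run, so no value within a run could be had.

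**Figure D2:**
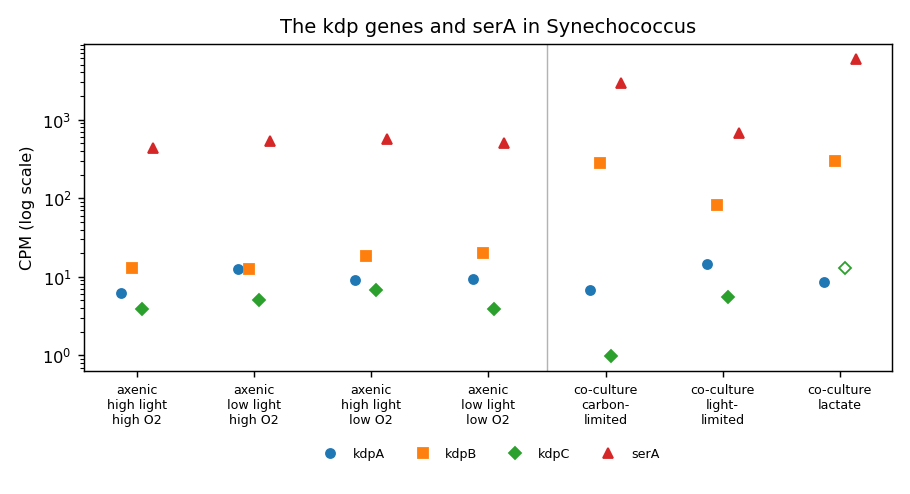
Levels of kdpA, kdpB, kdpC and serA in the 7 Synechococcus libraries, in CPM on a log axis, 1 point per library; the open symbol marks a count of 0, drawn at the 12.9 CPM that it allows. kdpB stood at 83.2 CPM or more in each co-culture and at 20.3 CPM or less in each axenic library, while kdpA stayed between 6.31 and 14.4 CPM.

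Between the lactate and the bicarbonate co-cultures, no Synechococcus gene passed the test. With the ratios to both bicarbonate co-cultures averaged, the lists of photosystem I, of ribosomal proteins and of glycogen and oxidative pentose phosphate genes lay low with lactate among matched random lists. psbF, a subunit of cytochrome b559 of photosystem II, had 4 reads with lactate and was 8.00-fold lower (95% interval 3.09 to 29.6) than in the carbon-limited and 10.2-fold lower (3.95 to 37.7) than in the light-limited co-culture. glmU, dusA and map, each on 3 reads with lactate, were 5.01-fold, 6.49-fold and 4.90-fold lower than in the carbon-limited co-culture. Compared with the light-limited one they were 5.97-fold, 4.12-fold and 4.08-fold lower. Photosystem I genes had a median log2 ratio of -0.94 (percentile 0.64, 6 members), ribosomal protein genes one of -0.53 (percentile 0.27) and glycogen and oxidative pentose phosphate genes one of -0.78 (percentile 1.90, 9 members). With lactate the glycogen list took 0.153% of the coding reads (95% interval 0.138 to 0.170). It took 0.162% in the carbon-limited and 0.269% in the light-limited co-culture, so its low rank cannot be laid to lactate alone. Photosystem I genes took 2.69%, 3.57% and 6.21% in this order, and ribosomal protein genes 2.37%, 2.55% and 2.94%. Photosystem II genes (median -0.44, percentile 9.36) and phycobilisome genes (median -0.56, percentile 13.2) were less extreme, and photosystem II genes took 6.11% of the coding reads with lactate, against 7.11% in the carbon-limited and 5.73% in the light-limited co-culture. Nitrogen assimilation genes had a median of 0.25 (percentile 99.1, 16 members, but 92.1 with 3 added to each count) and phosphate uptake genes one of 0.50 (percentile 97.4, 4 members). bicA and ftsH2 stood at 1981 and 2054 CPM with lactate, close to their 2041 and 2049 CPM under carbon limitation. By the 4-fold rule 1 gene was higher and 16 were lower with lactate than in both bicarbonate co-cultures. The reads that this rule needs on the higher side were present for 637 genes with lactate and for 2286 in both bicarbonate co-cultures. The counts of the directions thus cannot be set against each other.

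The fit across the 7 Synechococcus libraries called 0 of 3142 genes between lactate and bicarbonate co-cultures (edgeR, 406 at an unadjusted p under 0.05, lowest adjusted p = 0.211), and DESeq2 called 16. No list passed (lowest adjusted p = 0.526), and over the lists 0 genes passed among all genes tested and 4 when adjusted over the list alone. The ATP synthase list had a median of -0.10 and a test direction of higher. In simulated data the fit found 26.9% of genes changed 4-fold, with the 232209 reads of the lactate library as the smallest profile.

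Of the Shewanella genes with a symbol, metF and metL passed the test between co-culture and axenic culture, both close to the threshold and by a fit with 1 axenic library. metF (Sputw3181_3552, 4056047 to 4056934 on the minus strand), methylenetetrahydrofolate reductase, had a log2 change of -3.51 ± 0.93 (3 co-culture libraries against 1 axenic, adjusted p = 0.0457 by edgeR). metL (Sputw3181_3553), beside it, an aspartokinase and homoserine dehydrogenase, had one of -3.34 ± 0.89 (adjusted p = 0.0460). The fit assumes that the lone axenic library varies like the 3 co-culture libraries, and it cannot tell an effect of culture from a peculiarity of that library. metH, the cobalamin-dependent methionine synthase, named after its values were seen, had a log2 change of -2.86 ± 0.87 (adjusted p = 0.143), and the amino acid synthesis list did not pass (adjusted p = 0.112 by camera). metF stood at 1763 CPM in the axenic, 87.4 in the carbon-limited and 60.9 in the lactate profile. It had 6 reads in the light-limited profile, or 1075 CPM. The 5583 reads of that profile fitted a mixture of 46.5% axenic, 36.7% lactate and 16.8% carbon-limited profile.

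In all, 16 of 3926 Shewanella genes passed, 5 higher and 11 lower in co-culture, with 173 at an unadjusted p under 0.05. Of these, 11 had values that did not overlap, as did 34.9% of all tested genes, where chance would give 2 of 4 splits. The 2 lists that passed by camera rest on the same lone axenic library, so no change of a group by culture is concluded from them. Ribosomal protein genes had a median log2 change of 0.52 over 50 members, with 0 past the threshold (adjusted p = 6.82e-04, but 0.863 with an estimated correlation, 0.685 without the carbon-limited library and 0.0784 without the lactate library). Their share of coding reads was 13.0% in the carbon-limited and 10.6% in the lactate co-culture against 7.91% in axenic culture, but 7.59% (95% interval 6.91 to 8.32) in the light-limited co-culture. The cobalamin, biotin and thiamine list had a median of -1.25 over 5 members (adjusted p = 0.00235, but 0.631 with an estimated correlation and 0.685 without the carbon-limited library), with thiG at -1.82 ± 0.76 and cobT at -1.25 ± 0.80, named after their values were seen. Over the lists 2 genes passed among all genes tested and 4 when adjusted over the list alone. In simulated data 14 of 37 calls of this fit were false. edgeR called 574 genes without the carbon-limited library, 0 without the light-limited one (160 at an unadjusted p under 0.05; 17 by DESeq2) and 0 without the lactate one (71), and DESeq2 called 0 with all libraries (43 at an unadjusted p under 0.05).

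On lactate, where both Shewanella profiles were deep, 6 of 22 amino acid synthesis genes were at least 4-fold lower in co-culture than in axenic culture. metF was 28.9-fold lower (95% interval 26.0 to 32.3), metH 12.0-fold lower and metL 9.57-fold lower. The tryptophan synthesis genes trpC and trpD were 6.65-fold and 6.42-fold lower, and aroE, shikimate dehydrogenase, was 5.76-fold lower (4.95 to 6.73). glnA, glutamine synthetase, was 4.58-fold higher (4.36 to 4.82). The other 16 amino acid synthesis genes were not 4-fold apart, and the list's median log2 ratio was -0.20 (percentile 14.9 of matched random lists).

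In all, 109 of 4088 genes were 4-fold apart between the lactate co-culture and axenic Shewanella, 36 higher and 73 lower in co-culture. Ribosomal protein genes had a median log2 ratio of 0.39 (percentile 99.99 of matched random lists, 50 members). Fatty acid breakdown genes had a median of -1.72 (percentile 0.13, 5 members), cobalamin, biotin and thiamine genes one of -1.15 (percentile 0.24) and flagellar genes one of -0.31 (percentile 1.38, 36 members). With 1 library on each side no test was made, and the count was 449 at 2-fold and 28 at 8-fold.

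**Figure D3:**
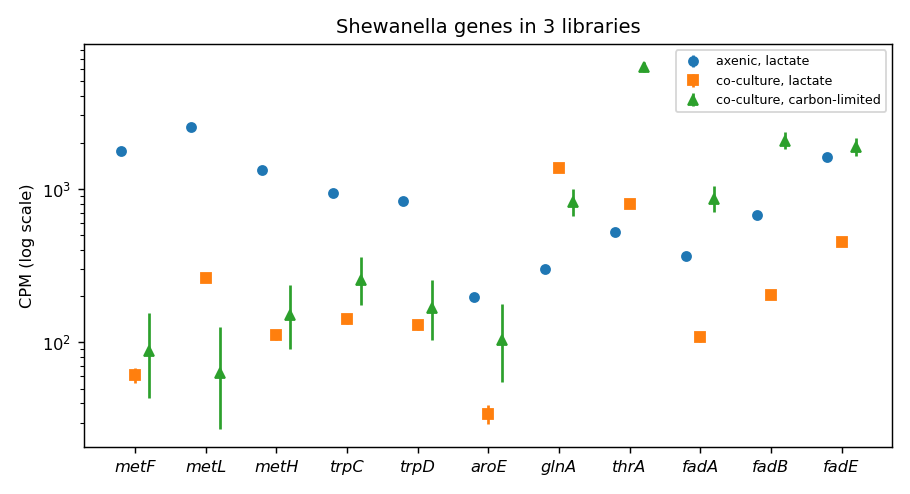
Levels of 11 Shewanella genes in the axenic, lactate co-culture and carbon-limited co-culture libraries, in CPM on a log axis, with 95% Poisson intervals of the counts where they exceed the symbol. metF stood at 1763 CPM in axenic culture and at 60.9 and 87.4 CPM in the co-cultures, while fadB stood at 2058 CPM in the carbon-limited co-culture and at 204 CPM in the lactate co-culture.

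Fatty acid breakdown genes of Shewanella were lower in the lactate co-culture than in the carbon-limited co-culture, which was fed bicarbonate. fadB (Sputw3181_0013) and fadA (Sputw3181_0012), the subunits of the fatty acid oxidation complex, were 10.1-fold (95% interval 8.78 to 11.5) and 7.92-fold (6.40 to 9.74) lower. fadE, an acyl-CoA dehydrogenase, was 4.17-fold lower, and thrA, of threonine synthesis, was 7.85-fold lower (7.26 to 8.47). The fatty acid breakdown list had a median log2 ratio of -2.06 (percentile 0.03 of matched random lists, 5 members). It took 0.106% of the coding reads in the lactate and 0.557% in the carbon-limited co-culture. In axenic culture, also taken as grown on lactate, it took 0.344%. The low level in the lactate co-culture thus cannot be laid to the carbon source alone. With lactate, thiH was 12.6-fold higher (4.93 to 46.4) on 4 reads in the carbon-limited library, and the ratio of thiG was 8.10 (2.76 to 39.3) on 3 reads. asnB, asparagine synthetase, was 5.34-fold higher, and pflA, hslU and metL were 4.54-fold, 4.45-fold and 4.15-fold higher; the ratio of gldA was 8.14 (3.37 to 101) on 2 reads.

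This comparison with the carbon-limited co-culture alone, with 82 genes higher and 17 lower with lactate, was added after the data had been seen. The 50 reads needed on the higher side were present for 3638 genes with lactate and for 474 under carbon limitation. The counts of the 2 directions thus cannot be set against each other. Against both bicarbonate co-cultures, as first planned, 0 of 4088 Shewanella genes were 4-fold apart. Only 5 genes had 50 reads in both bicarbonate profiles, so a lower level with lactate was mostly not detectable at this depth. A higher level was hard to detect as well, as 3 counts stand for 537 CPM in the light-limited profile. In simulated data the rule found 14.9% of genes changed 8-fold and 22.7% of those changed 16-fold. Against both bicarbonate co-cultures the fatty acid breakdown list had a median log2 ratio of -1.75 (percentile 0.055) and the amino acid synthesis list one of -0.92 (percentile 0.03, 22 members), on 11 and 57 reads in the light-limited profile, and with 3 in place of 0.5 added to each count the medians were -2.49 and -1.41.

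Between the bicarbonate co-cultures, the Shewanella profiles could be compared for abundant genes only, and the light-limited profile, which fitted a mixture of mostly axenic and lactate profiles (46.5% and 36.7%), may not stand for that co-culture. thrA was 6.93-fold higher under carbon limitation (95% interval 2.96 to 21.4), on 781 against 5 reads, and gltA, citrate synthase, was 4.29-fold higher (2.07 to 10.7) on 677 against 7 reads. rplU was 4.25-fold higher on 383 against 4 reads, and the ratios of rplM, rplK and rpsU, each with 3 reads under light limitation, were 4.75 (1.61 to 23.1), 4.63 (1.57 to 22.6) and 4.60 (1.56 to 22.4). Ribosomal protein genes, on 424 reads under light limitation, had a median log2 ratio of 0.87, above all matched random lists, with 0.5 added to each count, and one of 0.72 or 0.41 with 1 or 3 added. Fatty acid breakdown genes, on 11 reads there, had no stable median, with 2.20, 1.31 or -0.05. In all, 11 genes were higher and 3 lower under carbon limitation. The 3, named after their values were seen, were Sputw3181_0670 (3 against 72 reads), Sputw3181_3050 (518 against 93) and Sputw3181_4053 (559 against 112). The reads that the rule needs on the higher side were present for 474 genes under carbon limitation and for 6 under light limitation. The counts of the directions thus cannot be set against each other. With RLE size factors 64 genes were 4-fold apart, 63 of them higher under carbon limitation.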

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

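All tests of explanations in this part were chosen after the results had been seen.

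The light effect in axenic Synechococcus differed between the O2 levels for 19 genes by a test of the difference itself (edgeR, the third split of the 4 libraries). That test takes the light effect shared by both O2 levels as its spread, not that of repeat cultures. The log2 ratio of high to low light was 4.63 at high O2 and -3.49 at low O2 for bicA, 6.76 and -7.14 for SYNPCC7002_A0470, 0.68 and -1.45 for psbA, 0.87 and -1.11 for ftsH2, -1.63 and 2.52 for bchL, and -0.45 and 2.28 for katG. The difference of the single genes other than bicA and SYNPCC7002_A0470 did not pass that test.

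An exchange of the labels of the low-O2 pair would turn these opposite effects into like ones. It would also turn 12 genes that were at least 4-fold higher in high light at both O2 levels, such as SYNPCC7002_G0138 (34.0-fold and 7.44-fold), into opposite ones. As labelled, 25 were opposite among 2653 genes with at least 500 reads. Across these 2653 genes the log2 light ratios at the O2 levels correlated at Pearson -0.42 (Spearman -0.35). With an exchange the fit for light would call the 19 genes of the third split, and the third split the 0 genes of the fit for light. More genes were thus opposite as labelled, but a true reversal would give that too, and either labelling leaves a set of genes reversed. Exchanged labels and a true reversal cannot be told apart. A candidate explanation from the cells is a shared state of inorganic carbon supply. Of the 18 genes higher in the third split, 11 had a tested same-strand neighbour within 100 bases, in 17 pairs. In 12 of these pairs the neighbour was also among the 18, so the genes are not independent cases. All 18 were also at least 4-fold higher in the carbon-limited than in the light-limited co-culture, where 1.60% of all tested genes were, which is what this hypothesis needs under either labelling. Light dose, dilution rate and dissolved carbon were not given, so it stays a hypothesis.

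The share of reads in RNA genes of Synechococcus was 79.0% in the carbon-limited, 65.6% in the light-limited and 84.1% in the lactate co-culture, above the 39.5% that was the highest in axenic libraries. The Shewanella tRNA gene Sputw3181_R0090 had 28324 reads in the carbon-limited, 11534 in the light-limited and 3755 in the lactate co-culture, which was 938, 3251 and 1.56 times its share in the axenic library.

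In the light-limited co-culture the reads assigned to Shewanella were few, 5583 in coding genes, and Sputw3181_R0090 held 42.1% of all its Shewanella reads. Its light-limited to carbon-limited ratio was 0.407, near the 0.448 of the Synechococcus RNA reads and unlike the 0.118 of the Shewanella reads, so tRNA reads of Synechococcus may have been counted there. The coding reads, fitted as a mixture of the other Shewanella profiles, took 46.5% from the axenic, 16.8% from the carbon-limited and 36.7% from the lactate profile. The axenic percentage of the axenic and lactate parts was 55.9 (95% resampling interval 49.8 to 61.8), and the depths of those libraries would give 52.9, as reads carried over from them would. A true intermediate state of the few Shewanella cells stays open, and metF at 1075 CPM in that profile is a value that either could give.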

How the results depend on the processing

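The alternatives without the RNA-overlapping genes, with thinned reads, with DESeq2 on Shewanella without the light-limited library, with the carbon-limited co-culture alone, without Sputw3181_R0090, with other counts added in list medians and with 1 library left out for light or O2 were chosen after the data had been seen. For co-culture against axenic Synechococcus, 130 genes became 364 by DESeq2, 66 with reads thinned to the smallest library (fewer reads by construction), 21 with only the bicarbonate co-cultures, and 0 against the high-O2 or the low-O2 axenic libraries alone (496 and 588 at an unadjusted p under 0.05). Leaving out 1 library gave 0 to 356 genes, and scaling, filter and RNA alternatives gave 107 to 134. For light, edgeR's 0 genes became 11 without the filter, 22 by DESeq2 and 0 to 12 with 1 library left out. For O2, 4 became 14 by DESeq2 and 0 to 4 with 1 library left out, and acsF missed the threshold without the light term (adjusted p = 0.0675; over all alternatives 1.32e-72 to 0.655 for hemN and acsF). The leave-one-out fits for light and O2 had 1 term, as with both no residual degrees of freedom remain, and assume that the lone library of a class varies like the others. For lactate against bicarbonate co-culture of Synechococcus, 0 became 16 by DESeq2. For Shewanella against axenic, 16 became 0 by DESeq2 and 0 to 574 when 1 library was left out, and 17 by DESeq2 without the light-limited library. By the size rule, 0 Shewanella genes between lactate and both bicarbonate co-cultures became 11 at 2-fold, 1 at 10 reads, 2 with RLE and 99 against the carbon-limited co-culture alone; 84 Synechococcus genes between the bicarbonate co-cultures became 342 at 2-fold and 43 at 8-fold; 14 Shewanella genes there became 70, 2, 27 at 10 reads and 64 with RLE; and 109 between lactate co-culture and axenic became 449 and 28. The Shewanella share of 5.81%, 0.309% and 96.1% became 2.34%, 0.520% and 92.7% over all genes, 2.07%, 0.302% and 92.7% over all but Sputw3181_R0090, and 6.44%, 0.331% and 96.6% without the 10 most abundant genes of each organism. Upper-quartile scaling moved the median log2 change of all genes from -0.01 to -0.11 for O2 and from -0.10 to -0.20 for lactate against bicarbonate co-culture. The cause was not tested except where named. Named genes of the tests kept their direction in all 258 alternative values and missed the threshold in 127. The gene groups missed it in 10 of 41, 3 for Shewanella without the carbon-limited or the lactate library and 7 for O2 with 1 library left out. Of the 25 named genes of the planned comparisons by the size rule, 5 moved beyond their counting interval with RLE, all Shewanella genes between lactate co-culture and axenic, and none changed direction. For genes named in the comparisons added later, this alternative was not run. The planned pseudocounts were for normalized values only and were not run on counts. List medians had 0.5 added to each count: 1 moved 6 of 86, and 3 moved 16 and reversed 1, that of fatty acid breakdown in Shewanella between the bicarbonate co-cultures (2.20 to -0.0527). Of 26 medians in the outer 5% of random lists, 26 and 25 stayed there. Depth limits the light-limited profile of Shewanella most (5583 coding reads), then its carbon-limited profile (125840) and the lactate profile of Synechococcus (232209).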

Other observations

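All tests of explanations in this part were chosen after the results had been seen.

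In axenic Synechococcus, genes that followed the light label at both O2 levels included the cluster SYNPCC7002_A2657 to SYNPCC7002_A2662 and the plasmid genes SYNPCC7002_G0138 and SYNPCC7002_G0139. SYNPCC7002_A2662 was 11.5-fold and SYNPCC7002_G0139 44.6-fold higher in high light at high O2, and 4.10-fold and 9.49-fold higher at low O2. The same genes were higher in the light-limited than in the carbon-limited co-culture, SYNPCC7002_A2662 by 5.05-fold and SYNPCC7002_G0138 by 5.10-fold. Ribosomal protein genes had a median log2 light ratio of -0.13 at high O2 (percentile 0.63 of matched random lists) and of 0.47 at low O2 (above all of them). NDH-1 genes had medians of 0.43 and -0.95, and photosystem I genes of -0.41 and 0.06. psaA stood at 22112 CPM in high light and at 49317 CPM in low light at high O2.

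Across 2653 Synechococcus genes, the log2 ratio of the carbon-limited to the light-limited co-culture correlated with the third split of the axenic libraries (Pearson 0.61, Spearman 0.34), and less with light (-0.10, -0.12) or O2 (0.05, -0.14). These are correlations across genes, which are not independent replicates, and no p was computed.

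The difference between co-culture and axenic Synechococcus was larger than in other groupings. Of the 35 splits of the 7 libraries into 3 and 4, the real one gave 130 genes and the highest other gave 35. By chance the real split would come first in 1 of 35 cases. The other splits also mix the culture classes, which widens their spread and can lower their calls. Neither chance nor a difference between runs is thus excluded. For the 68 of the 105 higher genes with a tested same-strand neighbour within 100 bases, a change of whole operons is argued against. Their neighbours had a median log2 change of 0.00596 (upper quartile 0.38). The rest of the 105 had no such neighbour, so nothing is concluded for them, and no operon annotation was used. In the carbon-limited, light-limited and lactate libraries alone, the neighbours had medians of 0.04, 0.15 and -0.37. For the 25 lower genes, with -0.315 for the neighbours and -1.06 for the genes, a change of whole operons cannot be told. Shewanella reads counted in Synechococcus genes are argued against as well, as the excess in the carbon-limited co-culture was 0.748 times that with lactate (median of 103 genes), where the reads of the organisms would give 0.00252. In 2 of the genes, SYNPCC7002_A0224 and SYNPCC7002_A2239, which overlap tRNA genes, the ratio to the tRNA reads varied at most 1.52-fold over the 7 libraries, so these may count tRNA. For the rest, a larger share of short RNA in the co-culture libraries and a change in the cells cannot be told apart: 52.4% of the genes followed the order of RNA reads per coding read in the co-cultures, against 12.2% of the others, but that order is also that of the Shewanella share. Over all genes, the log2 changes of same-strand neighbours correlated at Pearson 0.22 for co-culture against axenic and 0.13 for lactate against bicarbonate co-culture. They correlated at 0.62 for light, 0.75 for O2, 0.75 for the third split and 0.78 for carbon-limited against light-limited co-culture. For each co-culture library alone against the axenic mean, the correlation was 0.40 (carbon-limited), 0.36 (light-limited) and 0.15 (lactate). The lactate library, with 232209 coding reads the smallest, is part of both low values. Why the culture and lactate values were lower was not tested.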
